A study of Mus musculus with 10 samples.

How the data were processed

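Transcripts were measured by RNA sequencing in 10 libraries from mouse heart tissue, 5 from the LPS group and 5 from the baicalin plus LPS group. Per the labels' protocols, RNA was extracted with TRIzol, and 1 µg of total RNA went into an ABclonal mRNA-seq library kit. Reads were assigned to the mm10 mouse genome build, per the submitters' processing notes. The aligner, the counting program, the gene annotation and the use of strand are not given in the sources used here. The design text also names a blank group given saline, which was not analysed here.

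The deposited count table held whole-number read counts for 31655 Ensembl gene IDs in each library, with no normalization by the authors. Totals ran from 39.4 to 75.7 M counts per library. Between 61.6% and 64.7% of the values from 1 to 50 in a library were even numbers, so a total is not a number of independently counted fragments, and counting intervals would be too narrow. The deposited FPKM table held FPKM values, fragments scaled by gene length and library total, for the same genes and libraries. Every FPKM value equalled the count scaled by 1 length per gene and the library total, within a relative deviation of 6.0e-15. It therefore added no measurement to the counts and served only as an alternative unit. All 20 columns of the 2 tables were mapped to a labelled sample, and 0 columns were left over.

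Gene symbols came from the GENCODE mouse release M21 table, which names 31076 of the IDs. The other 579 IDs kept their identifier and took between 0.0422% and 0.0668% of the counts of a library. Coordinates are those of the same annotation on GRCm38, the assembly also called mm10. Replicates are libraries labelled separately within a group. The design text speaks of 8 mice per group, but no label ties a library to a mouse, so p-values measure the spread between these libraries, which may be in part technical. No pair of libraries agreed within sampling noise, since the smallest chi-square per degree of freedom over genes with at least 10 counts in a pair was 15.2, for LPS libraries 1 and 3.

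The comparison was baicalin plus LPS against LPS, and every fold change is on the log2 scale in that direction. Raw counts were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMM factors, a robust fit and edgeR's own filter by group, which left 16850 genes. Tests were two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05 on the adjusted p. The standard error of a fold change was taken from the F statistic. Levels are counts-per-million (CPM) values scaled by TMM, given as mean ± SD over 5 libraries. The biological coefficient of variation over all genes was 31.4%.

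Gene lists were fixed before the data were examined: 22 pathway lists and 21 cell type marker lists. The pathway lists hold 704 genes, of which 698 were tested. The marker lists hold 220 genes, of which 171 were tested. The fixed symbols Ctgf and Cyr61 were matched to their current symbols Ccn2 and Ccn1. Lists with at least 5 tested members were tested with camera of limma 3.58.1 at a preset correlation between genes of 0.01, adjusted over the lists of one kind. That left all 22 pathway lists and 17 marker lists. The platelet, thymus, lung and airway, and sex-linked lists had too few tested members. Beside camera stand its p with the correlation estimated for each list, fry, and an exact permutation test of each library's list score, the mean log2 CPM of the members. An exact test of 5 libraries against 5 has 126 splits, so its smallest p is 0.00794.

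Genes are named by a rule with 4 parts, fixed before the data were examined. The first part names the 10 genes with the largest fold change in each direction among those past the threshold, with a mean CPM of at least 1 and a regular symbol, or, where fewer than 10 pass, up to 5 genes of smallest p in that direction. The second part names 21 genes of the redox, PI3K-AKT, inflammation and cardiac stress groups. The third part names up to 4 members of smallest p from the lists described gene by gene, and the fourth names the 5 genes of smallest p. Saa3, Lcn2, Serpina3n and Pdk4 were added after their values were seen. Some genes that the rule names are not reported here.

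On simulated counts for 16850 genes of this comparison, with 200 genes changed, the same steps recovered 59% of genes changed by 2-fold and 95% of genes changed by 4-fold. Of the calls, 3.15% were unchanged genes, and 0 genes were called with nothing changed. Camera called 0 of 20 random lists. The simulated genes were drawn independently, without the correlation between genes or the differences between libraries of a group seen in the data. These rates therefore cannot show how often genes or lists are falsely called in the real comparison.

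Alternatives were DESeq2's and upper-quartile factors, library totals, 2 other filters, a non-robust fit, DESeq2 1.42.0, limma-voom with and without sample quality weights, limma on log2(FPKM + 1) and log2(FPKM + 0.1), 1 surrogate variable from sva 3.50.0, a replicate block, and leaving out each library. Another 3 were added after the data were seen: leaving out LPS libraries 1, 2 and 3, leaving out baicalin plus LPS libraries 2 and 3, and leaving out mitochondrially encoded transcripts. Plots were drawn with matplotlib 3.10.9 under Python 3.11.15.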

Results

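Heart tissue of mice was profiled by RNA sequencing in 2 groups of 5 libraries. Per the design text, both groups received 10 mg/kg of lipopolysaccharide (LPS), a component of bacterial outer membranes that triggers systemic inflammation, by a single injection into the abdomen. Mice of the baicalin plus LPS group had received 100 mg/kg of baicalin, a plant flavone glucuronide, by gavage for 14 days before it, and mice of the LPS group had received water. Hearts were taken 72 hours after the injection. The LPS libraries held 62.3 ± 12.5 M counts (SD, n = 5) and the baicalin plus LPS libraries 51.8 ± 8.31 M (n = 5), a difference within the spread between libraries (two-sided exact permutation p = 0.135). Mitochondrially encoded transcripts took 39.1% ± 5.61 and 40.5% ± 2.89 of the counts (exact p = 0.651).

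The comparison asks which cardiac transcripts differ when baicalin precedes LPS, with redox balance and the PI3K-AKT pathway named in the study's title. The 4 genes of smallest p had lower values with baicalin and did not overlap between the groups. None of them passed the adjustment in edgeR, and DESeq2 called all 4, with adjusted p values of 2.83e-11 (Adgrf5), 1.35e-10 (Xdh), 1.18e-05 (Notch4) and 1.45e-05 (Timp3), as did the fits with sample quality weights and with 1 surrogate variable. The genes were picked by smallest p from the same counts, so these calls are not independent support. Xdh, which encodes the oxidant-producing enzyme xanthine dehydrogenase, had 214 ± 22.3 CPM in the LPS group and 119 ± 11.5 CPM with baicalin (n = 5 each), a log2 fold change of -0.85 ± 0.11 (SE, edgeR adjusted p = 0.110). Adgrf5, an adhesion G protein-coupled receptor, had 368 ± 37.1 and 216 ± 13.6 CPM (log2 fold change -0.77 ± 0.11, adjusted p = 0.110). Notch4, a Notch receptor of endothelial cells, had 37.5 ± 6.65 and 19.4 ± 2.43 CPM (-0.95 ± 0.14, adjusted p = 0.144). Timp3, an inhibitor of matrix metalloproteinases, had 224 ± 38.4 and 122 ± 12.3 CPM (-0.87 ± 0.14, adjusted p = 0.193). Agap2 had 11.01 ± 2.02 and 5.35 ± 1.26 CPM (-1.04 ± 0.19, adjusted p = 0.201).

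**Figure D1:**
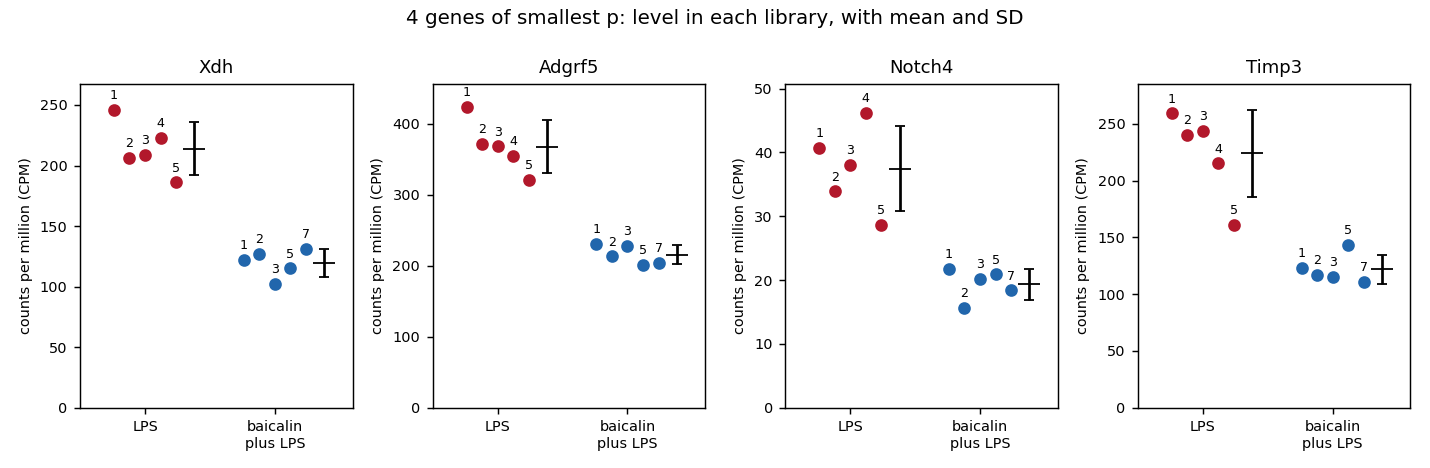
Levels of Xdh, Adgrf5, Notch4 and Timp3 in CPM on linear axes, with 1 point per library, marked by its replicate number, and the mean and SD of 5 libraries beside each group. Every baicalin plus LPS library lies under every LPS library: for Xdh the highest with baicalin is 131 CPM and the lowest without it 186 CPM.

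Among genes with higher values with baicalin and a mean of at least 1 CPM, the smallest p values belonged to Abracl, Ggh, Meis2, Tceal8 and Tmsb10. None of them passed in edgeR. From the same counts that were used to pick them, DESeq2 called all 5, with adjusted p values of 3.37e-05, 0.000348, 0.000457, 0.000268 and 0.00269. Abracl had 8.89 ± 0.869 and 14.1 ± 1.30 CPM (log2 fold change 0.66 ± 0.11, edgeR adjusted p = 0.193). Tmsb10, an actin-binding thymosin, had 23.2 ± 2.86 and 37.2 ± 6.73 CPM (0.68 ± 0.13, adjusted p = 0.204). Meis2, a homeobox transcription factor, had 24.8 ± 2.18 and 33.8 ± 1.51 CPM (0.45 ± 0.09). Ggh, Tceal8 and Vstm5 had log2 fold changes of 0.61, 0.45 and 2.17, the last at levels under 1 CPM. On GRCm38, Xdh (ENSMUSG00000024066) lies on chromosome 17 from 73883895 to 73950196, Adgrf5 (ENSMUSG00000056492) on 17 from 43360451 to 43459557, Notch4 (ENSMUSG00000015468) on 17 from 34564268 to 34588503 and Timp3 (ENSMUSG00000020044) on chromosome 10 from 86300372 to 86349506. Counts were deposited per gene ID, and which parts of a gene were counted is not given. Timp3 lies inside Syn3 on the opposite strand, where reads cannot be told apart without strand, and Syn3 itself had 0.933 ± 0.276 CPM in the LPS group. Xdh and Adgrf5 each overlap a small annotated gene on their own strand, and Notch4 and Abracl one on the opposite strand.

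Of the 16850 genes tested, 0 passed an edgeR adjusted p of 0.05, and 1878 had an unadjusted p under 0.05 against 842 given by chance, 887 of them higher and 991 lower with baicalin. Leaving out 1 library at a time gave between 1282 (without LPS library 3) and 3112 genes (without LPS library 4) at that unadjusted p. Other tools gave other counts at the same adjusted threshold: DESeq2 called 267 genes, limma-voom 0, limma-voom with sample quality weights 2974, and edgeR with 1 surrogate variable 71. The groups did not overlap in 415 genes, which is 2.46% of those tested against 0.794% by chance. Over all genes the libraries of the groups were not separated (exact permutation p = 0.127, one-sided, 16 of 126 splits).

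LPS libraries 1, 2 and 3 stood apart from the other 7 libraries in transcripts of the acute-phase response. Lcn2, which encodes the iron-carrier-binding protein lipocalin 2, had 6.41, 5.45 and 5.28 CPM in them, 1010 and 406 CPM in LPS libraries 4 and 5, and from 135 to 795 CPM in the 5 baicalin plus LPS libraries. Saa3, a serum amyloid A protein, had 2.23, 1.32 and 2.37 CPM in the same 3 libraries, 365 and 232 CPM in LPS libraries 4 and 5, and from 72.6 to 186 CPM with baicalin. Serpina3n had 14.7, 14.1 and 11.4 CPM, then 935 and 596 CPM, and from 234 to 642 CPM with baicalin. The group comparison gave no call for Lcn2 (log2 fold change 0.30 ± 1.29, edgeR adjusted p = 0.954), Saa3 (0.03 ± 1.27) or Serpina3n (0.40 ± 1.10). On the first principal component, with 39.4% of the variance, LPS libraries 1, 2 and 3 lay at -53.7, -57.2 and -59.3, LPS 4 at 76.3, and the other 6 between 4.76 and 24.8.

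**Figure D2:**
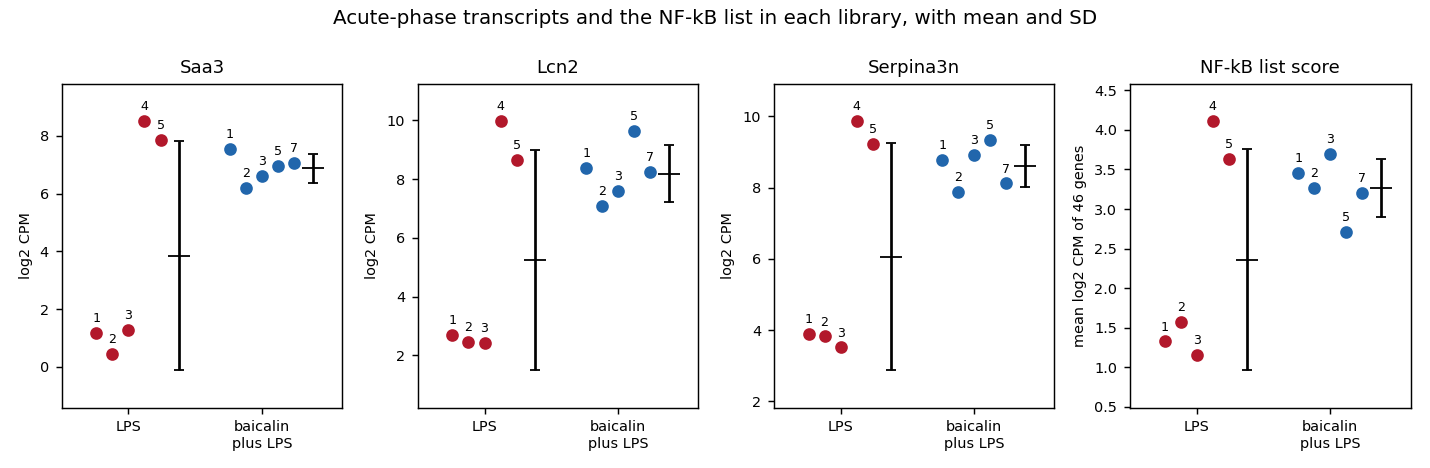
Saa3, Lcn2 and Serpina3n in log2 CPM and the NF-kB list score, the mean log2 CPM of 46 genes, with 1 point per library, marked by its replicate number, and the mean and SD of each group. LPS libraries 1, 2 and 3 lie lowest in every panel, with NF-kB scores of 1.33, 1.57 and 1.16, and baicalin plus LPS libraries lie between 2.71 and 3.69.

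The redox genes did not move together. Of 49 antioxidant enzymes and NRF2 targets tested, 25 had positive and 24 negative fold changes, 0 passed over all genes in edgeR or DESeq2, against 18 with quality weights and 1 with 1 surrogate variable, and 0 passed adjusted over the list alone (camera adjusted p = 0.792; 0.920 as adjusted p with an estimated correlation). The smallest p values of the list belonged to the glutaredoxin gene Glrx (0.67 ± 0.18), Txnrd2 (-0.35 ± 0.11), Txn2 (-0.32 ± 0.12) and Sod3 (0.63 ± 0.24). Superoxide dismutase Sod1 had 151 ± 48.3 CPM in the LPS group and 151 ± 38.1 CPM with baicalin, and Sod2 had 422 ± 74.1 and 344 ± 38.8 CPM (log2 fold change -0.29 ± 0.14, edgeR adjusted p = 0.478). The catalase gene Cat had 0.09 ± 0.35, the glutathione peroxidase gene Gpx4 -0.14 ± 0.11, Nqo1 0.32 ± 0.38, and Nfe2l2, which encodes the regulator NRF2, -0.17 ± 0.17. Hmox1, the heme-degrading oxygenase, had 338 CPM in LPS library 4 and between 12.7 and 67.3 CPM in the other 9 libraries. The 14 NADPH oxidase and oxidant-producer genes tested were not called as a list (11 positive, 3 negative, camera adjusted p = 0.192), and Nox4 had 0.91 ± 0.46 and Maoa 0.44 ± 0.17. Of them, 1 gene, Xdh, passed adjusted over the list alone (adjusted p = 0.000127), and Cybb, the catalytic subunit of the phagocyte oxidase, had 14.1 ± 11.6 and 31.2 ± 14.9 CPM (1.15 ± 0.56, adjusted p = 0.472). The antioxidant list was called lower with baicalin without LPS libraries 1, 2 and 3 (camera adjusted p = 0.0121) and higher without LPS library 4 (0.0264). LPS libraries 1, 2 and 3 had the lowest antioxidant scores, 5.144, 5.085 and 5.087 against 5.199 to 5.86 in the others. Leaving them out raises the LPS level by selection, so the call without them cannot show a direction for baicalin. The oxidant-producer list was called higher without LPS library 4 (0.0129).

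The PI3K-AKT components were called lower with baicalin by a small margin. Of 49 genes tested, 33 had negative and 16 positive fold changes, with a median log2 fold change of -0.15 (camera adjusted p = 0.00272, fry adjusted p = 0.0125). With an estimated correlation the adjusted p was 0.201. The list scores overlapped between the groups (exact permutation p = 0.167, and 0.451 after adjustment over the pathway lists). In edgeR 0 members passed over all genes and 0 adjusted over the list alone, while DESeq2 called 1 member over all genes, Tsc2 (adjusted p = 0.00137), quality weights 16 and 1 surrogate variable 0. Akt1 had 129 ± 15.6 CPM in the LPS group and 114 ± 10.5 CPM with baicalin (-0.18 ± 0.11, edgeR adjusted p = 0.585), and Akt2 141 ± 16.4 and 122 ± 5.03 CPM (-0.21 ± 0.10). The catalytic subunit genes Pik3ca, Pik3cd and Pik3cg had -0.15 ± 0.12, 0.41 ± 0.34 and 0.95 ± 0.46, and the adaptor gene Pik3ap1, chosen after its value was seen, 1.38 ± 0.61. Pik3cd, Pik3cg and Pik3ap1 are known mainly from leukocytes, and macrophage markers were called higher (18 of 19; adjusted p = 0.373 with an estimated correlation), but not without LPS libraries 1, 2 and 3 (adjusted p = 0.570). The smallest p values of the list belonged to Tsc2 (-0.32 ± 0.08), the brake on mTOR signalling, Pik3r3 (0.50 ± 0.14), Kdr (-0.47 ± 0.14) and Igf1r (-0.28 ± 0.09). Kdr is also on the endothelial marker list, which was called lower (12 of 14; adjusted p = 0.147 with an estimated correlation). The PI3K-AKT call was lost without baicalin plus LPS libraries 2 and 3 (camera adjusted p = 0.0572). Transcript levels do not report phosphorylation of the pathway's proteins.

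Targets of FOXO transcription factors, which AKT restrains, were called lower (22 of 25 genes, median -0.32, camera adjusted p = 2.2e-06; adjusted p = 0.300 with an estimated correlation). Ulk1, a kinase that starts autophagy, had -0.52 ± 0.13, Gadd45b -0.54 ± 0.19, Cited2 -0.55 ± 0.20 and Klf15 -0.68 ± 0.29, and 0 members passed in edgeR over all genes or adjusted over the list alone, while DESeq2 called Ulk1 over all genes. The FOXO call was lost without LPS libraries 1, 2 and 3 (adjusted p = 0.229) and without baicalin plus LPS libraries 2 and 3 (adjusted p = 0.0529). Pdk4, a starvation-induced brake on glucose oxidation, had 142 and 105 CPM in baicalin plus LPS libraries 2 and 3 and at least 1090 CPM in the other 8 libraries.

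Inflammatory genes were called higher with baicalin, but the direction turned without the 3 LPS libraries of low acute-phase transcripts. Of 46 genes of NF-kB cytokines and acute inflammation, 28 had positive and 18 negative fold changes (camera adjusted p = 0.000128), and with an estimated correlation the adjusted p was 0.618. Tlr2, a receptor for bacterial lipoproteins, had 4.19 ± 2.31 and 11.9 ± 6.08 CPM (1.51 ± 0.45, edgeR adjusted p = 0.301), Casp1 1.06 ± 0.32, Il18 1.13 ± 0.50 and Vcam1 0.81 ± 0.39. The cytokine genes Tnf (0.88 ± 0.90), Il1b (0.54 ± 0.58) and Il6 (-0.59 ± 0.60) had standard errors about as large as their fold changes, at mean levels under 4 CPM. Of 41 interferon response genes 26 had positive fold changes, and the list was called higher (camera adjusted p = 0.00294; 0.618 as adjusted p with an estimated correlation). When LPS libraries 1, 2 and 3 were left out, both lists were called lower with baicalin. Camera adjusted p values at the preset correlation were 7.91e-16 for NF-kB and 4.04e-06 for interferon. These libraries were picked for low Saa3, Lcn2 and Serpina3n, which are on the NF-kB list. They were the 3 lowest for 33 of 46 NF-kB and 29 of 41 interferon genes. Leaving them out raises the LPS level of both lists by selection and keeps only 2 LPS libraries. The turn therefore cannot show a direction for baicalin. Leaving out LPS library 1 or 3 alone ended the interferon call (adjusted p = 0.0600 and 0.198). Leukocyte markers moved along: macrophage (18 of 19) and neutrophil (9 of 14) lists were called higher (0.373 and 0.407 as adjusted p with an estimated correlation). Without LPS libraries 1, 2 and 3 the neutrophil list was called lower (adjusted p = 0.0111) and the macrophage call ended (0.570). These libraries were also the 3 lowest for 12 of 14 neutrophil markers, so the same limit holds for that list.

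MHC class II genes, which present antigen to helper T cells, were called lower (7 of 10, camera adjusted p = 0.0105; adjusted p = 0.618 with an estimated correlation). Cd74 had 36.8 ± 13.3 and 18.7 ± 3.19 CPM (-0.98 ± 0.25), H2-Ab1 -1.22 ± 0.33, H2-Aa -1.34 ± 0.41 and H2-Eb1 -1.06 ± 0.43. Of the 10, 0 passed in edgeR over all genes and 3 adjusted over the list alone, and DESeq2 called Cd74 and H2-Ab1 over all genes. Dendritic cell markers were called lower too (5 of 6, camera adjusted p = 0.00544; adjusted p = 0.147 with an estimated correlation), while macrophage markers were called higher (adjusted p = 1.16e-08; 0.373 as adjusted p with an estimated correlation). Of the dendritic cell markers, Zbtb46 had the smallest p (-0.54 ± 0.12) and Itgax alone went up (0.47 ± 0.40), both chosen after their values were seen. Whether the number of dendritic cells differed was not tested. The MHC class II call ended without baicalin plus LPS library 5 (adjusted p = 0.105), without library 7 (0.102), and without LPS libraries 1, 2 and 3 (0.896).

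Energy and contraction genes were called lower with baicalin. Of 56 nuclear genes of oxidative phosphorylation, 51 had negative fold changes, with a median of -0.24 (camera adjusted p = 8.5e-09). Ndufs7, a complex I subunit, had 130 ± 24.5 and 87.2 ± 10.5 CPM (-0.58 ± 0.15, edgeR adjusted p = 0.278), Cox4i1 -0.41 ± 0.13, Ndufs8 -0.47 ± 0.14 and Uqcrc1 -0.44 ± 0.14. Of 23 sarcomere genes, 20 had negative fold changes (adjusted p = 9.73e-06), among them Lmod2 (-0.51 ± 0.16), Myl3 (-0.59 ± 0.21) and Myom2 (-0.44 ± 0.17). Of 28 glycolysis and glucose uptake genes, 19 were negative (adjusted p = 0.00142), among them Aldoa (-0.36 ± 0.12), Pgam2 (-0.37 ± 0.13), Pfkl (-0.33 ± 0.12) and Hk2 (-0.56 ± 0.20). With estimated correlations the adjusted p values of the 3 lists were 0.618, 0.300 and 0.300, and 1 sarcomere gene and 0 genes of the other lists passed adjusted over the list alone. LPS libraries 1, 2 and 3 had the highest sarcomere scores (10.8, 10.7 and 10.9 against 10.2 to 10.5 elsewhere), and without them none of the 3 lists was called (adjusted p = 0.787, 0.851 and 0.0692). Cardiomyocyte markers were called lower too (8 of 10, camera adjusted p = 0.00127, or 0.407 with an estimated correlation), and not without these 3 libraries (adjusted p = 0.311). That list shares Myh6, Tnnt2, Tnni3, Actc1, Myl3 and Ttn with the sarcomere list, so its call in large part repeats the same genes. Without baicalin plus LPS libraries 2 and 3 the oxidative phosphorylation call also ended (adjusted p = 0.137). Of 51 genes of fatty acid use 35 had negative fold changes, and the list was called lower (camera adjusted p = 0.00975; 0.618 as adjusted p with an estimated correlation), and higher without baicalin plus LPS libraries 2 and 3 (adjusted p = 0.00985). Leaving out LPS library 5, baicalin plus LPS library 2 or library 3 alone ended that call (adjusted p = 0.121, 0.298 and 0.701).

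Cell cycle genes gave the smallest p of all lists in camera at the preset correlation, but not with an estimated correlation or in the exact test. Of 40 genes tested, 39 had positive fold changes, with a median log2 fold change of 1.22 (camera adjusted p = 6.09e-18), and with an estimated correlation the adjusted p was 0.300. In edgeR 0 passed over all genes and 26 adjusted over the list alone, while over all genes DESeq2 called 9, Birc5, Cdc6, Nusap1 and Kif11 among them, quality weights 10 and 1 surrogate variable 0. Birc5, a regulator of chromosome segregation, had 0.998 ± 0.207 and 2.98 ± 1.90 CPM (1.58 ± 0.43, edgeR adjusted p = 0.299), and Cdc6 (1.58 ± 0.44), Nusap1 (1.42 ± 0.40) and Kif11 (1.42 ± 0.41) were alike. The list score was 2.68, 2.81 and 3.33 in baicalin plus LPS libraries 1, 2 and 3, but 1.35 and 1.53 in libraries 5 and 7, within the LPS range of 1.30 to 1.75 (exact permutation p = 0.119). Macrophage and monocyte marker scores were highest in the same 3 libraries, at 4.02, 4.66 and 4.67, against 2.31 to 3.77 in the other 7.

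Extracellular matrix genes were called higher (38 of 50, camera adjusted p = 0.000927; adjusted p = 0.618 with an estimated correlation). Of these, Col3a1 had 59.3 ± 37.4 and 216 ± 196 CPM (1.86 ± 0.67), Col1a1 1.35 ± 0.51 and Col5a1 0.76 ± 0.30, while Timp3 went the other way and alone passed adjusted over the list. The direction turned without LPS libraries 1, 2 and 3 (lower, adjusted p = 0.0177), and the call ended without baicalin plus LPS library 3 alone (adjusted p = 0.154) or libraries 2 and 3 (0.330). LPS libraries 1, 2 and 3 had the lowest scores of the list, 3.96, 3.89 and 3.82. Leaving them out raises the LPS level by selection, so the turn shows no direction for baicalin. The scores of baicalin plus LPS libraries 2 and 3, which carried atrial transcripts, were the highest of all, 5.14 and 5.54, against 3.82 to 5.12 in the others. Fibroblast markers were called higher too (10 of 12, camera adjusted p = 0.0159; adjusted p = 0.547 with an estimated correlation), with the highest scores, 6.53 and 6.80, in the same 2 libraries.

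Glucocorticoid-induced genes were called lower with baicalin (18 of 20, median -0.53, camera adjusted p = 5.23e-07; adjusted p = 0.300 with an estimated correlation). Ddit4, an inhibitor of mTOR signalling induced by stress, had 62.5 ± 16.7 and 30.5 ± 6.40 CPM (-1.03 ± 0.20, edgeR adjusted p = 0.201). Zbtb16 had 173 ± 40.7 and 66.6 ± 28.8 CPM (-1.37 ± 0.32), Sult1a1 -0.52 ± 0.12 and Errfi1 -0.55 ± 0.19. The groups did not overlap in Ddit4, Zbtb16 and Sult1a1, and these 3 passed adjusted over the list alone. The list score overlapped between the groups (exact permutation p = 0.389) and was lowest in baicalin plus LPS libraries 2 and 3, at 4.75 and 4.63. Circadian clock genes were called lower too (16 of 21, camera adjusted p = 0.00272; 0.300 as adjusted p with an estimated correlation). Per2 had 46.01 ± 12.3 and 24.8 ± 3.74 CPM (-0.89 ± 0.19), Cry2 -0.48 ± 0.13 and Bhlhe41 0.41 ± 0.13, and the first 2 passed adjusted over the list alone. Without LPS libraries 1, 2 and 3 the glucocorticoid list was still called lower (adjusted p = 4.45e-10) and the circadian call ended (adjusted p = 0.982). Glucocorticoid scores in these 3 libraries were 5.483, 5.243 and 5.345, below the 6.603 and 6.265 of LPS libraries 4 and 5. Leaving them out therefore raises the LPS level by selection, and the smaller p does not strengthen the call.

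Endothelial markers were called lower with baicalin, and with TMM scaling this list separated the groups completely. Of 14 markers, 12 had negative fold changes, with a median of -0.33 (camera adjusted p = 3.99e-05; adjusted p = 0.147 with an estimated correlation). The list score was 6.51 ± 0.137 in the LPS group and 6.18 ± 0.0774 with baicalin (n = 5 each), lower in 5 of 5 libraries than in any LPS library (exact permutation p = 0.00794, the smallest possible, and 0.135 after adjustment over 17 lists). With library totals in place of TMM the scores overlapped (exact permutation p = 0.159), with a difference of -0.25 in place of -0.33 (log2). Tie1, an endothelial receptor kinase, had 71.0 ± 9.68 and 48.6 ± 6.36 CPM (-0.55 ± 0.12, edgeR adjusted p = 0.248), Esam -0.57 ± 0.13, the water channel gene Aqp1 -1.51 ± 0.42 and the VEGF receptor gene Flt1 -0.79 ± 0.23. With Kdr, 5 markers passed adjusted over the list alone, whereas Pecam1 (-0.05 ± 0.17), Emcn (0.21 ± 0.17) and Vwf (0.26 ± 0.34), chosen after their values were seen, did not. The call held without LPS libraries 1, 2 and 3 (adjusted p = 0.0014).

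**Figure D3:**
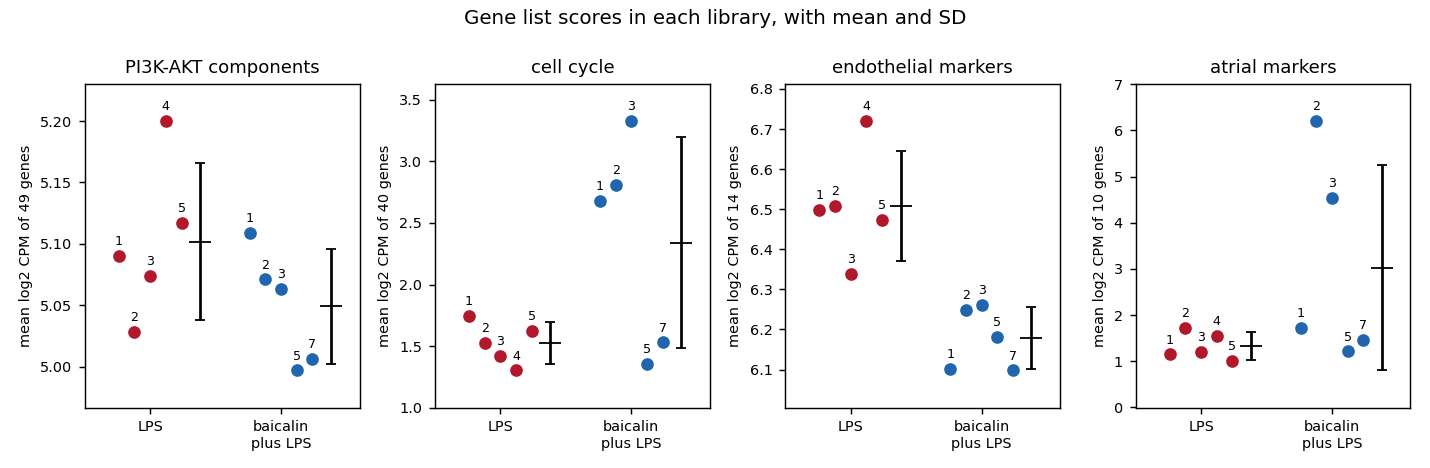
Scores of the PI3K-AKT, cell cycle, endothelial and atrial lists, each the mean log2 CPM of its members, with 1 point per library, marked by its replicate number, and the mean and SD of each group. Endothelial scores, on the TMM scale, do not overlap between the groups, and the atrial list is high in baicalin plus LPS libraries 2 and 3 alone, at 6.20 and 4.53.

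Atrial cardiomyocyte markers were called higher (10 of 10, camera adjusted p = 0.000143; adjusted p = 0.407 with an estimated correlation), from baicalin plus LPS libraries 2 and 3. Myl7, the atrial light chain, had 132 and 27.7 CPM there and at most 2.23 CPM in the other 8 libraries. Bmp10 had 65.7 and 12.1 CPM, Sln 56.5 and 11.2, and Myl4 170 and 38.8, and 7 of the 10 markers passed adjusted over the list alone. The natriuretic peptide gene Nppa, on the same list, had 789 and 254 CPM there, and 103 ± 24.6 CPM in the LPS group (1.45 ± 0.56, edgeR adjusted p = 0.378). Nppb had 0.72 ± 0.29 and Myh7 0.07 ± 0.58. Without those 2 libraries the atrial list was not called (adjusted p = 0.657).

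Cardiomyocyte markers were called lower (8 of 10, camera adjusted p = 0.00127; adjusted p = 0.407 with an estimated correlation). Ckm, the muscle creatine kinase, had 985 ± 338 and 522 ± 35.2 CPM (-0.92 ± 0.22), Ttn -0.49 ± 0.19 and Mb -0.53 ± 0.26. Their scores were 12.1, 12.1 and 12.2 in LPS libraries 1, 2 and 3 and 11.1 to 11.6 elsewhere, and the call ended without these 3 libraries (adjusted p = 0.311). Macrophage and monocyte markers were called higher (18 of 19, median 0.84, adjusted p = 1.16e-08; 0.373 as adjusted p with an estimated correlation). Lyz2, the macrophage lysozyme, had 123 ± 66.5 and 452 ± 285 CPM (1.88 ± 0.50, edgeR adjusted p = 0.299), Cx3cr1 2.80 ± 0.69, Ms4a7 1.66 ± 0.52 and the complement gene C1qa 0.96 ± 0.35. The macrophage call ended without the same 3 libraries (adjusted p = 0.570).

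Erythroid markers were called lower (7 of 7, median -2.02, adjusted p = 8.2e-06; 0.354 as adjusted p with an estimated correlation). The hemoglobin gene Hbb-bs had 84.9 ± 59.0 and 20.9 ± 10.3 CPM (-2.02 ± 0.62), and Hba-a1 had 217 CPM in LPS library 4 and 3.97 CPM in LPS library 5. Hemoglobin genes have near-identical copies, so the share of each copy, Hbb-bt (-2.08 ± 0.73) included, is uncertain. Fibroblast (10 of 12, camera adjusted p = 0.0159), neutrophil (9 of 14, 0.000143) and mesothelial (8 of 9, 0.00514) marker lists were called higher, and dendritic cell (5 of 6, 0.00544) and skeletal muscle (9 of 10, 0.00175) lists lower. With an estimated correlation the adjusted p values of these 5 lists were 0.547, 0.407, 0.407, 0.147 and 0.354. With LPS libraries 1, 2 and 3 left out, the neutrophil list was called lower (adjusted p = 0.0111), and the fibroblast (0.418), mesothelial (0.212) and dendritic (0.0992) calls ended. The fibroblast call also ended without baicalin plus LPS library 2 or 3 (adjusted p = 0.205 and 0.310), the mesothelial call without LPS library 4 or baicalin plus LPS library 2 (0.121 and 0.0824), and the skeletal muscle call without baicalin plus LPS libraries 2 and 3 (0.0790), as did the fibroblast (0.129) and mesothelial (0.0507) calls.

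In all, 14 of 22 pathway lists and 10 of 17 marker lists were called with the preset correlation, and 0 of either kind with an estimated correlation. Fry's test of a shared direction called 1 pathway list, PI3K-AKT, and 0 marker lists. Its test of change in either direction called 0 pathway lists and 3 marker lists, endothelial (adjusted p = 0.00176), dendritic cell (0.00371) and skeletal muscle (0.0257). In edgeR no list held a gene that passed over all genes. DESeq2 called 27 of the 698 genes of the pathway lists and 15 of the 171 of the marker lists, quality weights 278 and 60, and 1 surrogate variable 6 and 4. In edgeR adjusted over the list alone, at least 1 gene passed in 8 pathway and 8 marker lists, among them 1 of calcium handling, 1 cardiomyocyte, 2 macrophage, 1 B cell, 2 dendritic cell, 5 erythroid and 1 skeletal muscle gene. The cardiomyocyte and the skeletal muscle gene were the same, Ckm, which is on both lists.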

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

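The rule used in this part was fixed before the data were examined, and was applied to Saa3, Lcn2, Serpina3n and Pdk4 after their values were seen. In 290 groups of 5 values (104 genes, 39 list scores and 2 library measures, in each of 2 groups), 5 held a library far from the other 4, where about 1 in 20 is given by chance, or 14. Tmsb10 was 5.61 (log2 CPM) in baicalin plus LPS library 3 and 4.99 to 5.16 in the others of its group, a gap of 0.729 of the range. Nfe2l2 was 7.31 in LPS library 4 and 6.50 to 6.70 in the others, a gap of 0.75. Il6 was 0.26 in baicalin plus LPS library 2 and -1.77 to -1.19 in the others, a gap of 0.713. Cited2 was 5.41 in baicalin plus LPS library 5 and 4.55 to 4.75 in the others, a gap of 0.767. Il18 was -1.68 in baicalin plus LPS library 5 and -0.30 to 0.08 in the others, a gap of 0.784. The rule looks for 1 distant library, so it does not see the 3 LPS libraries or the 2 baicalin libraries that stand apart together.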

How the results depend on the processing

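Leaving out LPS libraries 1, 2 and 3, leaving out baicalin plus LPS libraries 2 and 3, and leaving out mitochondrially encoded transcripts were chosen after the data were seen. The count of 0 genes at an adjusted p of 0.05 held with 3 other scalings, a stricter filter, a non-robust fit, limma-voom, FPKM, the 3 sets left out, and each library left out (0 to 0, higher and lower). It became 267 with DESeq2 (115 higher, 152 lower), 2974 with limma-voom and sample quality weights (1593 higher, 1381 lower), 71 with 1 surrogate variable (22 higher, 49 lower), 2 with no filter (0 higher, 2 lower, Xdh and Notch4) and 867 at an unadjusted p of 0.05 with 1.5-fold. The quality weights ran from 0.160 for LPS library 4 to 3.17 for LPS library 1. The cause was not tested, beyond the splits given under the other observations. Separation gave exact p values of 0.135 with 500 genes and 0.151 with rank correlation.

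Pathway lists called went from 14 to 0 with an estimated correlation, 1 with fry and 0 with exact tests, and marker lists from 10 to 0, 0 and 0. Without LPS libraries 1, 2 and 3 the marker lists were 5. Leaving out each library gave 12 to 20 pathway and 10 to 12 marker lists. The replicate block over the 8 libraries with shared numbers gave 0 genes, 20 pathway and 11 marker lists, against 19 and 11 for the same libraries unblocked. No sign of pairing by number was seen: deviations of same-numbered libraries correlated at -0.104, 0.0762, -0.0393 and 0.0517, and none correlated best with its own number. LPS libraries 1, 2 and 3 were nearly alike (Spearman correlations of 0.9929 to 0.9935), so their deviations are similar. The check therefore cannot exclude pairing.

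Of the alternative values of 104 named genes, 2707 kept their direction and side of the threshold, 135 kept the direction and passed it, and 62 reversed. The cause was not tested. Without LPS libraries 1, 2 and 3 the log2 fold changes became 0.11 (Pik3ca), -0.17 (Pik3cd), -0.26 (Nqo1), -0.35 (Sod1), 0.017 (Sod2), -0.39 (Cat), -0.27 (Tnf), -0.061 (Il1b), -0.89 (Myh7), 0.022 (Klf15), 0.47 (H2-Eb1), 0.12 (Mb), -1.27 (Saa3), -0.99 (Lcn2) and -0.87 (Serpina3n). Without baicalin plus LPS libraries 2 and 3 they became -0.070 (Il1b), -0.067 (Nox4), -0.23 (Sln) and 0.061 (Pdk4). Hmox1 became 0.20 and 0.15 with FPKM at pseudocounts of 0.1 and 1, 0.15 also without a filter, 0.13 with limma-voom, 1.36 with quality weights, 1.18 with the replicate block and 0.78 in the same 8 libraries. Il6 became 0.19, 0.048 and 0.15 in the last 3, Nfe2l2 0.012 with quality weights, Saa3 -0.070 with library totals, and Sod1 -0.033 with 1 surrogate variable, -0.0020 with DESeq2, -0.0020 with its factors and -0.0018 with no filter. Leaving out each library gave ranges of -0.24 to 0.0077 (Nfe2l2), -1.36 to 0.65 (Hmox1), -0.028 to 0.54 (Nqo1), -0.12 to 0.21 (Sod1), -0.18 to 0.26 (Cat), -1.20 to 0.033 (Il6), -0.16 to 0.63 (Myh7), -0.28 to 1.05 (Saa3) and -0.24 to 1.74 (Lcn2). LPS library 4 alone turned Nfe2l2, Hmox1 and Il6. Xdh, Adgrf5, Notch4 and Timp3 kept their direction in all 28 alternatives, with adjusted p from 1.35e-10 to 0.559 for Xdh. With 5 libraries per group the simulated 2-fold changes were recovered in 59% of genes, and smaller changes were not simulated.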

Other observations

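The tests of the library and marker patterns in this part were chosen after the results were seen, as was the choice to count splits for DESeq2 and the quality weights. Several lists were not called. Cell death and ferroptosis genes had 24 of 32 positive fold changes (camera adjusted p = 0.0779), immediate early genes 19 of 27 negative (0.0779), and unfolded protein and heat shock genes 18 of 29 negative (0.128). Leaving out libraries brought calls in the same directions. The unfolded protein list was called lower without LPS library 2 (0.0394), baicalin plus LPS library 1 (0.0285) or 7 (0.00923), or LPS libraries 1, 2 and 3 (0.0383). The immediate early list was called lower without LPS library 1 (0.0184), 2 (0.00804) or 3 (0.00436), all 3 of these (6.79e-09), or baicalin plus LPS library 1 (0.0180) or 7 (0.0274), and with library totals (0.0344). The cell death list was called higher without LPS library 4 (0.00266) or 5 (0.0302) and with the stricter filter (0.0437). Calcium handling genes gave an adjusted p of 0.733, cardiac stress genes 0.283, and mitochondrially encoded transcripts 0.733, with a negative median and test and a positive mean. Leaving out LPS library 4 alone brought calls for calcium handling (lower, 0.0253), cardiac stress (higher, 0.00735) and mitochondrially encoded transcripts (lower, 0.0253). Leaving out LPS libraries 1, 2 and 3 turned all 3 calls, to calcium handling higher (0.0159), cardiac stress lower (0.0383) and mitochondrially encoded transcripts higher (4.95e-05). Cytosolic ribosomal protein genes were called higher (36 of 44, adjusted p = 0.000335; 0.618 as adjusted p with an estimated correlation), and lower without LPS libraries 1, 2 and 3 (adjusted p = 0.0383). These 3 libraries were picked from the data, and leaving them out keeps only 2 LPS libraries. Calls made without all 3, that of the immediate early list included, therefore show no direction for baicalin. Among markers, mural (adjusted p = 0.0785), T and NK cell (0.101), B cell (0.208), mast cell (0.0528), adipocyte (0.208), lymphatic endothelial (0.429) and Schwann and neuronal (0.939) lists were not called, the last with a positive median and mean and a negative test. The mural list was called lower without LPS library 1 (0.0348) or 5 (0.0490) or baicalin plus LPS library 2 (0.00542) or 3 (0.0161), and with the stricter filter (0.0128). The mast cell list was called lower without LPS library 2 (0.0476) or 5 (0.0378) or baicalin plus LPS library 2 (0.00542) or 3 (0.00583), and with upper-quartile factors (0.0362) or library totals (0.0202). The T and NK cell list was called higher without LPS library 4 (0.0211) or baicalin plus LPS library 1 (0.00732) or 5 (0.00602), and the adipocyte list higher without baicalin plus LPS library 1 (0.0314) or 7 (0.00547). Without baicalin plus LPS libraries 2 and 3 the mural (0.00134), mast cell (0.000133), B cell (0.0199), lymphatic endothelial (0.0121), Schwann and neuronal (0.0350) and adipocyte (0.0350) lists were called lower.

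Of the lists too small to test, the platelet gene Pf4 had 130 to 1239 counts per library. The thymus genes Rag1 and Ptcra had at most 2 counts, and the lung gene Sftpc at most 2. The airway gene Scgb1a1 had 48 counts in baicalin plus LPS library 2 and at most 2 elsewhere. All 10 libraries had between 16366 and 25765 counts of Xist, and at most 18 of the Y-linked Ddx3y. These genes were chosen after their values were seen.

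LPS libraries 1, 2 and 3 had low acute-phase transcripts. Scaling of the libraries is excluded as the cause: Lcn2 spanned 7.49 (log2) over the 5 LPS libraries under whichever scaling gave the least, while scaling factors spanned at most 0.437. Labels swapped between the groups stay open: 0 baicalin plus LPS libraries lay at or under the level of these 3, which an exchange of whole groups would give too. Such an exchange would not by itself explain why these 3 differ from the other libraries of their group. A label from outside, a missed injection and a response that had resolved by 72 hours may each account for the low transcripts, and cannot be told apart: all predict that NF-kB genes are lowest there, as 30 of the 43 other than Saa3, Lcn2 and Serpina3n were, in libraries picked from the same data, and no blank library was analysed here.

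Baicalin plus LPS libraries 2 and 3 carried atrial transcripts. A stress programme in ventricular muscle is argued against by 1 of 16 cardiac stress genes outside the atrial list having these libraries as its highest pair. Atrial tissue in the dissected piece is a candidate explanation that stays untested, since the 7 of 10 atrial markers with them as the highest pair are the pattern itself. The mix of atrium in a piece could then move other lists, such as the extracellular matrix and fibroblast lists, with these libraries, and within a group the design gives no biological explanation to test. Between the 2 libraries those scores did not rise with the atrial score, which was 6.20 in library 2 and 4.53 in library 3. Extracellular matrix scores were 5.14 and 5.54 there, and fibroblast scores 6.53 and 6.80.

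The endothelial marker list was called lower with baicalin at the preset correlation, but not with an estimated one (camera adjusted p = 0.147). The 3 LPS libraries with low acute-phase transcripts are argued against as the whole cause, but weakly: the list was still called lower without them (camera adjusted p = 0.0014 at the preset correlation). That setting also called a median of 7 marker lists in splits with LPS libraries 1, 2 and 3 on 1 side, and 6 in splits that parted them. Scaling of the libraries stays open for the separation: the score remained lower under all 3 other scalings, but with library totals, which shifted the median gene by 0.081 (log2), its exact p was 0.159 and the groups overlapped. A smaller endothelial share of the tissue and lower transcription per cell cannot be told apart: a smaller share predicts that the markers move alike, and the spread of the 14 differences, from Aqp1 (-1.51 ± 0.42) to Vwf (0.26 ± 0.34), gave an exact p of 0.0635 against other splits. Any effect of baicalin on these markers is untested beyond the group comparison, where the exact test of the list score gave an adjusted p of 0.135.

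Other splits of the 10 libraries into 5 and 5 show how far chance can be excluded. The count of 0 genes at an adjusted p of 0.05 cannot be tested so, since any split gives at least 0, as 100 of 100 did, and the highest other gave 1. For 1878 genes at an unadjusted p of 0.05, chance cannot be excluded: 12 of 100 splits gave as many, up to 3085. LPS libraries 1, 2 and 3 fell on 1 side in 11 of these 12 and in 17 of the 100, so the count follows that structure. For 14 pathway lists 23 of 100 splits gave as many, up to 18, and for 10 marker lists 9 of 100, up to 12, so chance cannot be excluded for either count. With sample quality weights 13 of 100 splits gave 2974 genes or more, up to 4051, every time with LPS libraries 1, 2 and 3 on 1 side, and at most 1 gene was called in a split that parted them. For 415 genes without overlap, 6 of 126 splits gave as many, which excludes chance at 0.05 over all splits. The highest other, LPS libraries 1, 2 and 3 with baicalin plus LPS libraries 2 and 3, gave 1628, several times the real count, which points to a structure of the libraries. All 6 were among the 21 splits with LPS libraries 1, 2 and 3 on 1 side, and within these chance cannot be excluded. For the 267 genes of DESeq2, 1 of 30 splits, the real one, gave as many, and the highest other gave 162, which excludes chance at 0.05 over those splits. Only 4 of the 30 kept LPS libraries 1, 2 and 3 on 1 side, with 267, 162, 132 and 38 genes, against at most 80 in splits that parted them, and 4 splits are too few for a share under 0.05. All 267 had an unadjusted p under 0.05 in edgeR, 253 were also called with quality weights and 43 with 1 surrogate variable.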
